A study of Mus musculus with 6 samples.

How the data were processed

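Polyadenylated or total RNA selection is not given in the sources used here. Per the labels' protocols, lung tissue was lysed in TRIzol, RNA integrity was checked on agarose gels, libraries were sequenced on an Illumina NovaSeq instrument, and cleaned read pairs were aligned with HISAT2 2.0.5. The genome build is mm10, per the submitters' processing notes. The program that counted reads per gene, the gene annotation and the use of strand are not given in the sources used here. Coordinates are printed as the deposited table gives them.

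The authors deposited 1 table of FPKM values for 54532 genes in 6 libraries, with gene identifier, symbol, position, length and class per gene. In every library, 100% of the values above 0, multiplied by the gene length of the table, were whole multiples of a single step within a tolerance of 0.01, so whole reads could be recovered. The step was set by a library size, which was the product of median-of-ratios size factors, recomputed from the recovered reads, and the geometric mean of the library totals. The scaling sizes ran from 16959288 to 17361949. The recovered totals ran from 16649061 to 17456715 reads per library, and 3 reads on a gene of 1 kilobase correspond to 0.173 to 0.177 FPKM. Intervals on reads cover counting error only.

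Spreadsheet dates had replaced 27 gene symbols, which were restored from gene identifiers. Of the identifiers, 54409 (99.8%) were found in the reference name table. Symbols repeated on 203 rows were kept apart by their identifier, and Aldoa denotes the row of ENSMUSG00000030695. All columns of values belong to a labelled sample. Groups were taken from the age label of each sample.

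The libraries were compared before averaging. Over genes with at least 50 reads in a pair, chi-square per degree of freedom lay between 2.25 and 4.93 for pairs of the same group and between 76.8 and 81.6 for pairs of different groups, so no pair of replicates was within sampling noise, and each library was counted as 1 sample.

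Values were transformed to log2(FPKM + 1). Genes with an FPKM of at least 0.5 in at least 3 of the 6 libraries were tested, 15197 in all. The comparison of the libraries labelled aged with those labelled young used limma 3.58.1 in R 4.3.3, with a linear model on group, empirical Bayes moderation with a mean-variance trend, 2-sided p-values and Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and the count of genes changed at least 2-fold is on that scale. Folds printed for single genes are ratios of mean FPKM. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 53 lists with at least 5 tested members. The same test with an estimated correlation and limma's fry were alternatives. Fry asks whether the members of a list move, without comparing them with other genes. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

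The tests, the 73 gene lists (1684 entries, of which 2 found no row and 7 were matched through a synonym), the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 1 FPKM in the higher group and no overlap between groups. Antigen receptor segments, pseudogenes and genes known only by a clone or model name were left out there. To these were added up to 4 members with the smallest p from every list with a called set test or a called member, and 24 genes chosen in advance for senescence, lung cell types, matrix, blood, sex and heart. Genes named outside this rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

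Alternatives mostly changed 1 choice at a time: pseudocounts of 0.1 and 0.5, no filter or a mean of at least 1 FPKM, median centring, quantile normalization, rescaling to TPM, leaving out haemoglobin, immunoglobulin and mitochondrial genes with the rest rescaled to TPM, limma without the trend, with robust moderation or with array weights, protein-coding genes only, the replicate number as a block, leaving out each library, and thresholds of 0.1 and 0.01. Added after the data were seen were limma's voom on the recovered reads and leaving out both libraries with kidney transcripts.

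The fitting and set-test scripts were tested on simulated reads for the real genes of this comparison (15219 tested). Of 100 genes changed 1.5-fold, 71% were called, and of 100 changed 2-fold, 94% were called, with 14 false calls among 15019 unchanged genes. A list moved 1.2-fold was called in the right direction, and 0 of 20 lists left alone were called. Simulated genes were drawn independently of one another, with few of them changed. All shared 1 dispersion, a measure of spread between libraries, set at the median estimate of 0.000766. The list calls therefore do not measure false calls in lists of correlated members, and the gene calls do not cover genes that vary more.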

Results

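RNA from mouse samples whose labels name lung was profiled by RNA sequencing in 6 libraries. The labels place 3 libraries in a young group, from mice aged 3 months, and 3 in an aged group, from mice aged 18 months, and the design asks which transcripts differ between these ages. The deposited values are FPKM, fragments scaled by gene length and library size, for 54532 genes, of which 33676 were above 0 in at least 1 library. Whole reads recovered from these values summed to 17266815, 17456715 and 17398134 in the libraries labelled young and to 16887256, 16649061 and 16906850 in those labelled aged. At least 1 read was recovered for 24074 to 24363 genes per library labelled young and for 26703 to 26925 genes per library labelled aged. Across genes, log2(FPKM + 1) values correlated at Pearson's r of 0.989 to 0.990 within a group and 0.952 to 0.956 between groups, where genes are not independent replicates. The labels do not say whether the 3 libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

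Most transcripts that mark lung tissue were near 0 in all 6 libraries. Sftpc, the surfactant protein of alveolar type 2 cells (chromosome 14, 70520949 to 70524081 on the minus strand, mm10), had 4 reads over the 6 libraries and at most 0.112 FPKM in any of them. Scgb1a1, the secretoglobin of club cells, reached at most 0.855 FPKM, Foxj1, the transcription factor of ciliated cells, 0.0887 FPKM, and Ager, the receptor abundant on alveolar type 1 cells, 0.679 FPKM. Endothelial Pecam1 reached at most 0.322 FPKM, leukocyte Ptprc (CD45) 0.0953 FPKM and erythrocyte Hbb-bs 0.453 FPKM. Marker lists of lung epithelial, endothelial, mesothelial and blood cells, 22 in all, were fixed before the data were examined. The median of their 363 genes was 0.0908 FPKM, and 33 of them stood at 10 FPKM or more in every library. Alveolar type 1 cells were the least clear, with 6 of 15 markers at that level, among them Aqp5. Eln, the elastin gene, had 13 reads over the 6 libraries and heart muscle Myh6 had 40.

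The same libraries held most cell cycle transcripts, and some matrix and cytoskeletal transcripts, at high levels. Col1a1, the main chain of type I collagen, lay between 153 and 251 FPKM, and Mki67, the Ki-67 proliferation antigen, between 52.5 and 77.6 FPKM. Of the 40 genes of the cell cycle list, 38 stood at 10 FPKM or more in every library. Matrix lists were mixed, with 12 of 19 collagens, 13 of 34 elastic fibre and matrix glycoprotein genes and 9 of 23 basement membrane genes at that level. Other abundant transcripts, chosen after their values were seen, were Spp1 (osteopontin) at 1132 to 1819 FPKM, Fn1 (fibronectin) at 522 to 993 FPKM, Vim (vimentin) at 478 to 506 FPKM and Top2a (topoisomerase II alpha) at 112 to 121 FPKM. Xist, the RNA that coats the inactive X chromosome of female cells, reached at most 0.0908 FPKM and Y-linked Ddx3y at most 0.0447 FPKM. These contents go against the tissue label in all 6 libraries, so the groups are called labelled young and labelled aged throughout, and rose, fell, higher and lower describe the libraries labelled aged relative to those labelled young.

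**Figure D1:**
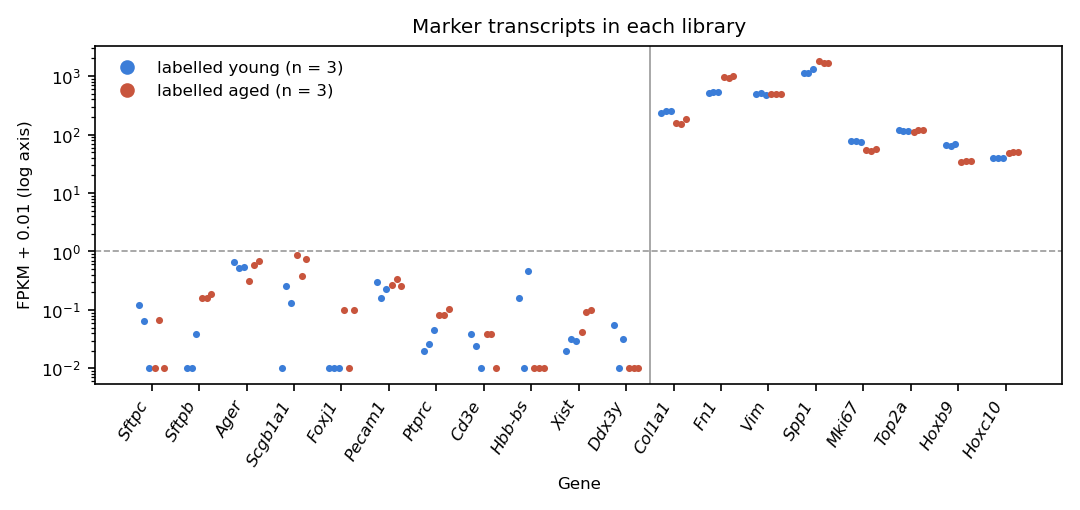
FPKM plus 0.01 on a log axis for 19 marker genes, with 1 point per library (3 labelled young in blue, 3 labelled aged in red) and a dashed line at 1 FPKM. All points of the 11 genes left of the vertical line, markers of lung epithelium, endothelium, leukocytes, erythrocytes and sex, lie under 1 FPKM, and all points of the matrix, proliferation and Hox genes on its right lie above 34 FPKM.

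The libraries labelled aged differed from those labelled young in a large share of their transcripts, among them higher p53 target, cell cycle and secretory factor genes and lower hypoxia, glycolysis and interferon genes. Ccng1, cyclin G1 and a direct p53 target (chromosome 11, 40748552 to 40755311, minus strand), rose 7.77-fold, from 32.5 ± 0.696 to 252 ± 10.2 FPKM (SD, n = 3 in each group here and below). Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, plus strand), rose 5.73-fold, from 14.9 ± 0.851 to 85.6 ± 1.70 FPKM. Car9, a carbonic anhydrase induced by low oxygen (chromosome 4, 43506966 to 43513729, plus strand), was 15.5-fold lower, at 7.14 ± 0.709 against 110 ± 16.4 FPKM. Ifi27l2a, an interferon-inducible gene, was 9.27-fold lower, at 55.6 ± 1.43 against 515 ± 56.1 FPKM. By limma, 9115 of 15197 tested genes changed at an adjusted p under 0.05, of which 4212 were higher and 4903 lower. This balance turned under some alternatives, as with median centring (4867 higher and 4174 lower) or no filter on low values (4814 and 4516). Of the 9115 genes, 736 changed at least 2-fold on the log2(FPKM + 1) scale, 428 higher and 308 lower. On that scale low genes fall short of a 2-fold ratio of FPKM, and the count was 1634 with a pseudocount of 0.1, 1358 after rescaling to TPM and 1791 with voom on recovered reads. Camera called 16 of 53 gene lists, of which none was called with an estimated correlation. The values of the groups did not overlap for 10161 genes (66.9% of those tested, where chance gives 10%).

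The hypoxia and glycolysis list fell in the libraries labelled aged, with 24 of its 26 tested members lower, 0 higher and 2 not past the threshold, and a median log2 fold change of -0.89. Adjusted over the list alone, 24 were lower and 1 higher. Camera called the list (adjusted p = 1.28e-08), and that call was lost at adjusted p = 0.434 with an estimated correlation. Pfkl, the liver-type phosphofructokinase of glycolysis, was 6.12-fold lower, at 10.2 ± 0.250 against 62.3 ± 4.82 FPKM (log2 fold change -2.50 ± 0.06 SE, limma adjusted p = 1.46e-06). The glycolytic enzyme gene Aldoa was 3.36-fold lower, at 127 ± 5.80 against 425 ± 26 FPKM, and P4ha1, a prolyl hydroxylase of collagen, was 2.89-fold lower, at 35.8 ± 1.81 against 103 ± 1.80 FPKM. Bnip3, a mitophagy receptor gene and hypoxia target, was 8.60-fold lower, at 5.37 ± 0.312 against 46.2 ± 10.7 FPKM.

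The list of DNA repair genes and p53 targets rose, with 26 of 36 tested members higher, 6 lower and 4 not past the threshold, the same counts when adjusted over the list alone. Camera gave adjusted p = 2.26e-05 for this list and adjusted p = 0.434 with an estimated correlation. Aen, an apoptosis-enhancing nuclease gene, rose 6.0-fold, from 4.84 ± 0.199 to 29.0 ± 1.33 FPKM. Mdm2, the ubiquitin ligase that degrades p53, rose from 12.2 ± 0.423 to 49.4 ± 2.01 FPKM, and Gtse1, a p53-regulated gene of G2 and S phase, rose from 17.5 ± 0.239 to 57.2 ± 2.0 FPKM. Trp53 itself rose 1.97-fold, from 39.1 ± 2.0 to 77.2 ± 3.41 FPKM (log2 fold change 0.96 ± 0.05 SE, limma adjusted p = 1.46e-05). The senescence regulators did not pass the set test (camera adjusted p = 0.897, 7 higher, 7 lower and 4 not past the threshold, with 8 lower when adjusted over the list alone), and their median, mean and test differed in sign. Lmnb1, lamin B1, fell from 83.9 ± 1.05 to 52.8 ± 3.61 FPKM. Cdkn2a, the p16 and p19Arf locus, had 11 reads in the libraries labelled young and 1 in those labelled aged, a ratio of 10.9 with an exact 95% counting interval of 1.58 to 469, and Cdkn2b had 1 read in all.

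**Figure D2:**
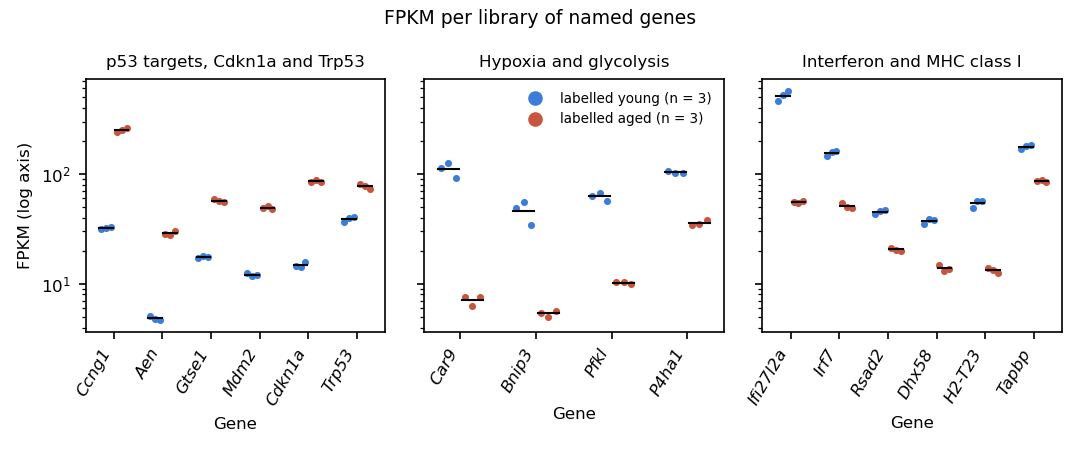
FPKM per library on a log axis for p53 targets with Cdkn1a and Trp53, for hypoxia and glycolysis genes, and for interferon and MHC class I genes. Points are the 3 libraries labelled young (blue) and the 3 labelled aged (red), and bars are group means. In each of the 16 genes no library labelled aged overlaps the libraries labelled young, with Ccng1 at 252 against 32.5 FPKM and Car9 at 7.14 against 110 FPKM on average.

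The cell cycle and proliferation list rose, with 31 of 40 tested members higher, 3 lower and 6 not past the threshold. Adjusted over the list alone, 32 were higher and 3 lower. The list had camera adjusted p = 5.55e-08, and adjusted p = 0.338 with an estimated correlation. Aurka, the mitotic Aurora A kinase, rose 1.98-fold, from 35.1 ± 0.671 to 69.4 ± 0.805 FPKM. Ccnb1, cyclin B1, rose 1.62-fold to 68.3 ± 1.29 FPKM, and Mcm7, a subunit of the replicative helicase, rose 1.63-fold to 59.9 ± 1.21 FPKM. Mki67, a member of the same list, went the other way and was 1.40-fold lower, at 54.3 ± 2.07 against 76.0 ± 1.87 FPKM.

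The interferon response list fell, with 38 of 46 tested members lower, 6 higher and 2 not past the threshold, both over all genes and adjusted over the list alone. For this list camera returned adjusted p = 5.55e-08, and adjusted p = 0.434 with an estimated correlation. Irf7, a transcription factor that drives type I interferon genes, was 3.02-fold lower, at 51.3 ± 2.75 against 155 ± 9.44 FPKM. Rsad2 (viperin), an antiviral enzyme, was 2.21-fold lower and Dhx58, an RNA sensor of the RIG-I family, 2.70-fold lower. MHC class I antigen presentation, which shares Tap1, Psmb8 and Psmb9 with the interferon list, fell as well. Of its 16 tested members, 12 were lower, 1 higher and 3 not past the threshold, the same when adjusted over the list alone. Camera gave adjusted p = 0.00166 for it and adjusted p = 0.434 with an estimated correlation. The non-classical class I gene H2-T23 was 4.06-fold lower, at 13.3 ± 0.689 against 54.1 ± 4.28 FPKM, and Tapbp (tapasin), which loads peptides onto class I molecules, was 2.04-fold lower. Class I genes resemble one another closely, so how reads were shared among H2-T22, H2-T23 and H2-T24 is uncertain.

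The list of senescence-associated secretory factors rose, with 19 of 23 tested members higher and 4 lower, the same when adjusted over the list alone. By camera these factors had adjusted p = 4.52e-05, and adjusted p = 0.434 with an estimated correlation. Gdf15, a stress-induced cytokine, rose from 27.9 ± 3.52 to 135 ± 12.9 FPKM, and Timp2, a metalloproteinase inhibitor, rose 2.79-fold to 289 ± 16.8 FPKM. Immediate early genes rose as a list, with 14 of 26 tested members higher, 4 lower and 8 not past the threshold, the same when adjusted over the list alone. The list had camera adjusted p = 0.0245, and adjusted p = 0.434 with an estimated correlation. Fosl1, a subunit of the AP-1 transcription factor, rose 2.53-fold and Klf4, a zinc finger transcription factor, rose from 3.85 ± 0.470 to 14.2 ± 0.365 FPKM, while the AP-1 gene Fosl2 fell from 35.0 ± 0.0868 to 19.9 ± 0.697 FPKM.

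Lysosome and autophagy genes rose, with 22 of 32 tested members higher, 3 lower and 7 not past the threshold, the same when adjusted over the list alone. Camera gave adjusted p = 7.13e-05 and adjusted p = 0.434 with an estimated correlation. Lamp1, a glycoprotein of the lysosomal membrane, rose 2.09-fold to 452 ± 6.95 FPKM, and Gpnmb, a transmembrane glycoprotein of lysosomes and melanosomes, rose 2.10-fold to 562 ± 17.6 FPKM. Cytosolic ribosomal proteins fell, with 39 of 78 tested members lower, 2 higher and 37 not past the threshold. Adjusted over the list alone, 35 were lower and 2 higher, and camera gave adjusted p = 0.000190 for the list and adjusted p = 0.566 with an estimated correlation. Rps6, of the small ribosomal subunit, was 1.61-fold lower, at 391 ± 1.92 against 629 ± 13.3 FPKM, and Rpl10, of the large subunit, was 1.65-fold lower. The abundant members Rplp0 and Rplp1 went the other way, at 1935 ± 104 against 1593 ± 67.3 FPKM and 1818 ± 188 against 1269 ± 130 FPKM. Ribosomal protein genes have many processed pseudogenes, among which the authors' counting could have split reads.

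Mitochondrially encoded genes rose, with 10 of 15 tested members higher, 1 lower and 4 not past the threshold, the same when adjusted over the list alone. As a set they had camera adjusted p = 0.00292, and adjusted p = 0.434 with an estimated correlation. The complex I subunit gene mt-Nd4 rose 1.76-fold to 789 ± 28.1 FPKM and mt-Nd6 rose 2.04-fold to 688 ± 24.8 FPKM, whereas the ribosomal RNA mt-Rnr1 fell from 625 ± 27.3 to 308 ± 19.4 FPKM. All mitochondrial genes together took 1.92% to 1.98% of reads in the libraries labelled aged and 1.45% to 1.55% in those labelled young.

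Collagen genes fell in the libraries labelled aged. Of 14 tested fibrillar and other collagens, 10 were lower, 3 higher and 1 not past the threshold, the same when adjusted over the list alone, with camera adjusted p = 0.0172 and adjusted p = 0.434 with an estimated correlation. Col3a1, the chain of type III collagen, was 3.24-fold lower, at 19.2 ± 0.459 against 62.3 ± 1.92 FPKM, and Col1a1 was 1.49-fold lower, at 164 ± 17.2 against 245 ± 8.45 FPKM. In the list of collagen processing and crosslinking, 13 of 21 tested members were lower, 3 higher and 5 not past the threshold, with 13 lower and 4 higher when adjusted over the list alone. Camera gave adjusted p = 0.0201 for that list and adjusted p = 0.434 with an estimated correlation. Plod1, a lysyl hydroxylase, was 2.78-fold lower and Loxl1, a lysyl oxidase-like crosslinking enzyme, was 1.92-fold lower. P4ha1, named above among hypoxia genes, is a member of this list too.

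Lipid metabolism genes were lower in 3 lists. Fatty acid oxidation and lipid storage had 18 of 27 tested members lower, 2 higher and 7 not past the threshold, with camera adjusted p = 0.000886 and adjusted p = 0.338 with an estimated correlation. Within it, Hadh, a dehydrogenase of mitochondrial beta-oxidation, was 2.42-fold lower and Acaa2, a mitochondrial thiolase, 1.92-fold lower. Cholesterol synthesis had 15 of 23 tested members lower, 5 higher and 3 not past the threshold, with camera adjusted p = 0.0250 and adjusted p = 0.546 with an estimated correlation. Srebf2, the transcription factor of sterol synthesis, was 2.51-fold lower, at 24.5 ± 1.38 against 61.7 ± 1.75 FPKM, and Sqle, squalene epoxidase, was 1.77-fold lower. The surfactant lipid list had 15 of 22 tested members lower, 2 higher and 5 not past the threshold, with camera adjusted p = 0.0172 and adjusted p = 0.434 with an estimated correlation. Its leading members, Elovl1 and Elovl6 (fatty acid elongases), Srebf1 (a lipogenic transcription factor) and Scd2 (a fatty acid desaturase), act in general fatty acid synthesis, and surfactant protein genes themselves were near 0. Counts adjusted over the list alone were the same in all 3 lists.

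The list of ion channels and transporters of fluid clearance rose, with 6 of 9 tested members higher, 0 lower and 3 not past the threshold, the same when adjusted over the list alone. This list had camera adjusted p = 0.0268, and adjusted p = 0.434 with an estimated correlation, and without a filter on low values adjusted p was 0.150. Aqp5, a water channel, rose from 56.6 ± 1.72 to 88.3 ± 5.05 FPKM, and Slc9a3r2, a scaffold protein of sodium-proton exchange, rose 2.21-fold to 5.75 ± 0.0667 FPKM.

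**Figure D3:**
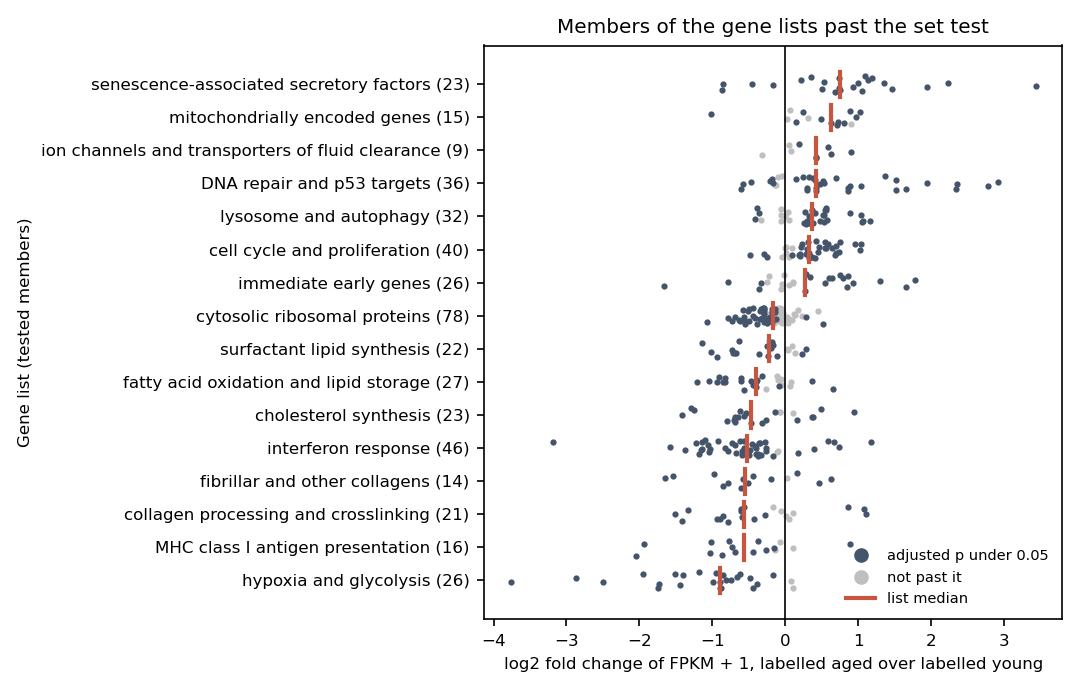
Log2 fold change of FPKM + 1, labelled aged over labelled young, for each tested member (point) of the 16 gene lists past the set test, with the number of tested members in parentheses. Dark points passed an adjusted p of 0.05 and grey points did not, and bars are list medians, which range from -0.89 for hypoxia and glycolysis to 0.75 for senescence-associated secretory factors.

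Among the 12 largest rises, Ces2e, a carboxylesterase gene of a family of related copies (chromosome 8, 104926260 to 104934672, plus strand), had 1889 reads in the libraries labelled aged against 3 in those labelled young, a ratio of 636 with an exact 95% counting interval of 217 to 3086. Cd80, a ligand of T cell costimulation, rose from 0.979 ± 0.247 to 16.2 ± 0.860 FPKM, Havcr2 (TIM-3), an immune checkpoint receptor, from 0.808 ± 0.115 to 11.2 ± 0.739 FPKM, and Tigit, another, from 1.01 ± 0.553 to 11.3 ± 0.651 FPKM. Hmga2, an architectural chromatin protein of developing and dividing cells, rose 7.26-fold to 83.0 ± 2.65 FPKM, and Eda2r, a receptor of the TNF receptor family, rose 11.5-fold to 14.5 ± 0.949 FPKM. Anxa8, a calcium-dependent phospholipid-binding protein, rose from 7 to 571 reads over the 3 libraries of a group. Ccng1 was also among them, as were Bglap2 (an osteocalcin gene), the histone gene Hist1h3g and the mitochondrial tRNA gene mt-Te, the last 3 of which are short or have near-identical or adjoining genes, so their read assignment is uncertain.

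The 12 largest falls included Ndufa4l2, a mitochondrial protein induced by low oxygen, which was 13.2-fold lower, at 6.53 ± 0.451 against 86.4 ± 16.4 FPKM. H1f0, the linker histone H1.0, was 9.41-fold lower, at 56.1 ± 2.65 against 528 ± 41.7 FPKM, and Ly6a, the surface protein Sca-1, was 7.71-fold lower, at 91.9 ± 7.88 against 709 ± 36.5 FPKM. Aldoc, an aldolase of glycolysis, was 9.57-fold lower, at 3.18 ± 0.436 against 30.4 ± 1.25 FPKM. Mir210, the gene of a microRNA induced by low oxygen, had 32 reads in the libraries labelled young and 2 in those labelled aged, both in aged 3, a ratio of 15.8 with an exact 95% counting interval of 4.04 to 136. Selenbp1, a selenium-binding protein, was 5.64-fold lower and Mpnd 5.54-fold lower, and Car9, Ifi27l2a, Bnip3 and Pfkl were also among the 12.

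No list of cell type markers passed the camera test among the 12 that had 5 or more tested members, and adjusted p over the 37 lists that did not pass ranged from 0.0825 to 0.948. In the monocyte list, 7 of 11 tested members were higher and 2 lower, or 7 and 3 when adjusted over the list alone (camera adjusted p = 0.0825, and 0.0329 with voom on recovered reads), led by matrix genes that other cells also make. These were Vcan (versican), which rose from 4.03 to 12.1 FPKM on average, and Fn1, which rose from 526 to 960 FPKM. In the list of alveolar type 1 cells, 4 of 9 were higher and 3 lower (adjusted p = 0.744, the same counts when adjusted over the list alone), with Pdpn (podoplanin) rising from 38.4 to 92.4 FPKM and Vegfa, a vascular growth factor, falling from 86.5 to 47.5 FPKM. In the list of alveolar type 2 cells, 1 of 6 was higher and 4 lower (adjusted p = 0.439, the same counts when adjusted over the list alone). Cd8a had 0 reads in all 6 libraries, and Cd3e, Gzmk and Jchain, markers of T cells, granzyme-bearing lymphocytes and plasma cells, had 7, 6 and 14 reads over the 6 libraries, too few to compare.

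Kidney transcripts, chosen after their values were seen, stood out in young 1 and young 3. Kap, an androgen-regulated protein of the renal proximal tubule, had 1409 reads in young 1, 267 in young 3 and 0 in the other 4 libraries. With both of these libraries left out, an alternative added after the data were seen that leaves 1 library labelled young, assumed to vary like those labelled aged, 6234 genes were called.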

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

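The voom fit and the fit without both libraries holding kidney transcripts were chosen after the data were seen, and all other alternatives were planned. The count of changed genes stayed within 1.5 times its value of 9115 under all 21 refits, from 6234 (without both kidney-bearing libraries, which leaves fewer samples) to 9510, and leaving out 1 library at a time gave 8155 to 8708 genes and 724 to 769 at 2-fold. At thresholds of 0.1 and 0.01 it was 10109 and 6992. The main calls kept in the same direction ranged from 66.5% to 99.9% of those tested, 1 call was called in the opposite direction under quantile normalization, and the higher share of calls ranged from 44.5% to 53.8% (46.2% as reported).

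The count at 2-fold, 736 as reported, was 1634 with a pseudocount of 0.1 and 1125 with 0.5. It was 1358 after rescaling to TPM, 1373 with haemoglobin, immunoglobulin and mitochondrial genes left out and the rest rescaled to TPM, and 1791 with voom. The pseudocounts and both rescalings lower the pseudocount relative to the values by construction. The voom fit ran on recovered reads, without the pseudocount of 1 FPKM. Whether this alone gives its count was not tested.

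Of 16 called lists, 15 kept their call and direction under every refit that tested them, and ion channels of fluid clearance lost it without a filter (adjusted p = 0.150, range over alternatives 0.0113 to 0.150). Of the lists not called, 4 were called in a refit: NF-kappaB (adjusted p = 0.0465), NRF2 (0.0267) and circadian genes (0.0443) without a filter, and monocytes with voom (0.0329). With an estimated correlation camera called 0 of 53 lists (5 at an unadjusted p under 0.05). Estimated correlations lay under the preset of 0.01 for fatty acid oxidation (-0.0228), immediate early genes (0.00349) and ion channels of fluid clearance (-0.0388). Correlation among members therefore does not account for the calls these lists lost there. The other called lists had estimates above the preset, from 0.0271 for the cell cycle list to 0.589 for hypoxia and glycolysis. How far correlation accounts for their losses was not tested. Fry called 44 by direction and 53 mixed, but it does not compare a list with other genes. What else accounts for these differences was not tested.

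Of 5084 refitted values for 243 called named genes, 5037 kept direction and call, 47 (20 genes) lost the call and 0 reversed. Ager, not called, stayed so in 20 refits, with the opposite sign in 2. With a replicate block, 8441 genes, 734 at 2-fold and 16 lists were called. Libraries with the same number did not deviate together (correlations of 0.0056, -0.0079 and 0.019), and the labels tie no numbers across groups. At 3 reads in a group, counting error sets the limit, as for Ces2e.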

Other observations

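Genes of the Hox clusters, the homeobox transcription factors that record position along the body axis, were chosen as a family after their values were seen, and no set test was run on them. Of 26 tested members, 11 were lower in the libraries labelled aged, 7 higher and 8 not past the threshold by limma, where 60% of all tested genes changed. Hoxb9 fell from 66.0 ± 2.53 to 34.5 ± 0.400 FPKM (SD, n = 3 per group), Hoxa9 from 13.9 ± 0.300 to 7.62 ± 0.364 FPKM and Hoxa10 from 23.8 ± 0.918 to 15.6 ± 0.824 FPKM, whereas Hoxc10 rose from 39.5 ± 0.278 to 50.1 ± 1.34 FPKM and Hoxb7 from 11.4 ± 0.357 to 18.9 ± 2.38 FPKM. None of these 5 changed sign in the 21 refits. The posterior gene Hoxb13 lay between 3.30 and 5.95 FPKM. Tbx4, Tbx5 and Foxf1, transcription factors of lung mesenchyme, reached at most 0.103, 0.0378 and 0.144 FPKM.

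Among long intergenic noncoding RNAs past the threshold, more were higher than lower in the libraries labelled aged. Of 624 tested lincRNA genes, 252 were higher, 76 lower and 296 not past the threshold, so 76.8% of calls were higher, against 44.3% of calls among protein-coding genes (3458 higher and 4343 lower). The lincRNA share ranged from 74.2% to 83.3% over the 20 refits that included them, and the protein-coding share from 43.3% to 51.9% over 21. Antisense and processed transcripts each had 62.9% of calls higher. The class was chosen after its values were seen, and no set test was run on it. Detection also rose in silent genes such as olfactory receptors. Their rate of reads, fitted to the number of genes with a read, went from 0.0254 to 0.0574 per kilobase.

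The tests on library contents, kidney transcripts and gene detection were chosen after the values were seen, and the splits of the libraries were planned. The 6 libraries fall into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 9115 genes, 736 at 2-fold and 16 lists, and 1 split of the 10, the real one, gave results of that size. The other 9 gave 0 genes, 0 at 2-fold and 6 to 9 lists, where limma left 153 to 200 genes at an unadjusted p under 0.05. Each side of these 9 splits holds libraries of both labels. Part of the difference between the labelled groups therefore enters their spread, and part stays in the comparison. For this reason they are no reference for the 9115 genes or the 16 lists. Why they still called 6 or more lists was not tested.

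All 6 libraries nearly lacked most lung transcripts. Loss of lung genes during counting would leave their rows empty. Yet 91.5% of 363 genes in the 22 fixed lists of lung and blood cell types, on 20 chromosomes, received reads, with a median of 0.0908 FPKM. A single read in any library sufficed, as 18879 of 22046 protein-coding genes had. This goes against empty rows, but partial loss was not tested. Lung tissue with another mix of cells would carry Xist or Y-linked transcripts at 1 FPKM or more. Yet Xist, Ddx3y, Uty, Kdm5d and Eif2s3y reached at most 0.0908 FPKM in any library. The criterion was not applied to cells grown in culture, which may carry the same transcripts, so it does not favour them. A candidate explanation is dividing mesenchymal cells grown in culture: 38 of 40 cell cycle genes stood at 10 FPKM or more in every library, beside Col1a1 at 153 FPKM or more, Fn1 at 522 or more and posterior Hox genes. Whether the deposited table belongs to another experiment than the labels stays open, and so does whether the groups differ by age or by a condition the labels do not name.

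Young 1 and, less so, young 3 held kidney transcripts. Kidney markers, 36 in all, were listed after the first of them were seen. Of these, 14 had 10 or more reads in young 1 and at most 2 in young 2 and in each library labelled aged. In 6 fixed lists of other organs the count was 0, but genes on the kidney list had first been taken out of them. Cyp2e1, on both the kidney and the liver list, was counted for kidney only. These 14 markers took 176 CPM in young 1, 42.1 CPM in young 3 and 0.601 CPM or less elsewhere, led by Kap (1409 reads), Acsm2 (419) and Pck1 (257). The 14 came from 3 nephron segments, 12 of them from the proximal tubule. Umod alone was from the loop of Henle, Klk1 alone from the distal tubule and 0 from collecting duct or podocytes. The list itself held 20 proximal tubule markers and 4 of each other segment. Distal tubule Kl and Calb1 had 62 and 27 reads in young 1 and 0 in young 2. They missed the cut only through 5 and 3 reads in aged 3. All 14 markers also had 3 or more reads in young 3. With so few markers outside the proximal tubule, kidney genes switched on in the cells of young 1 and young 3 stay open. Kidney RNA carried into these libraries, or reads assigned to them from a kidney library, may be the source, and of 12 Y-linked reads over the 6 libraries all were in these libraries, but no test here parts those routes. The ratio of young 1 to young 3 ranged from 2.60 to 7.64 over 11 markers, so a single kidney sample need not account for both.

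More genes were detected in the libraries labelled aged, at 26703 to 26925 against 24074 to 24363. Depth does not account for this: with all libraries thinned to 16649061 reads, the lowest library labelled aged still exceeded the highest labelled young by 2457 genes. Detection was expressed as the rate of reads per kilobase that gives the observed number of genes with a read if reads fall evenly. Genomic DNA would raise this rate alike in all classes. The rise in lincRNAs (from 0.284 to 0.431 per kilobase) was 4.61 times that in olfactory receptor genes and 8.28 times that in vomeronasal receptor genes, but 0.739 times that in keratin-associated protein genes (from 0.121 to 0.320). Processed pseudogenes rose from 0.391 to 0.462 and snRNAs went from 1.11 ± 0.0442 to 1.13 ± 0.0437 per kilobase (SD, n = 3). Several of these classes lie near the floor and pull apart, so DNA in the libraries labelled aged stays open. A wider range of transcription in the libraries labelled aged, through age or another condition, may account for it and was not tested.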
